A study of Homo sapiens with 6 samples.

How the data were processed

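RNA was taken from A375 melanoma cells transduced with a lentivirus for GFP (3 libraries) or for murine BMI1 (3 libraries). Per the labels' protocols, total RNA was extracted with TRIzol, purified on columns and made into libraries with a standard Illumina protocol. Whether the kit selected poly(A) RNA or kept strand, and the read length, are not given in the sources used here. The deposited table holds estimated counts per gene symbol as RSEM gives them, with 2 decimals, for 23345 gene symbols in 6 columns, and 0 columns were left unused. The submitters' processing notes name RSEM 1.2.12, Bowtie 1.0.1 and the genome build hg19, without their settings. The values are not normalized. No coordinates are given, because the annotation at hand belongs to another genome build.

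Each library was placed in its group by its title in the labels, and column names were matched to the labels. Both groups carry replicate numbers 1, 2 and 3, and nothing in the labels says that a number marks a shared culture, day or batch, so the numbers were not used to pair libraries in the main result. Depth ran from 20221432 to 30388937 estimated counts per library. A row with 0 counts allows up to 3 counts, which is 0.148 CPM in the shallowest library and 0.0987 CPM in the deepest. Such limits and the binomial interval cover counting error only.

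The estimated counts were rounded to whole numbers. Of the rows, 3468 were empty in all libraries, and edgeR's filterByExpr with its defaults kept 15079 genes. Libraries were scaled by TMM and tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the tested genes (edgeR 4.0.16, R 4.3.3), at a threshold of 0.05. Adjusted p-values of single genes come from this test unless another tool is named. Log2 fold changes are BMI1 over GFP, the standard error is the fold change divided by the square root of the F statistic, and CPM values are TMM-scaled means with SD over 3 libraries. The common biological coefficient of variation was 5.93%.

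Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 31 lists of at least 5 tested genes that are not markers of other cell types. Beside it stand the numbers of members past edgeR's threshold over all genes and adjusted over the list alone. The lists hold 899 genes and were written from general knowledge, with the series title known. They cover Polycomb complexes, CDK inhibitors, HOX genes, melanoma states, matrix, signalling, drug response, stress and metabolism, and markers of keratinocytes, fibroblasts, leukocytes and endothelium. Some genes stand in more than 1 list.

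The groups, the tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The rule named BMI1. It also named the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. In each list it named up to 4 members with the smallest adjusted p that passed. It also named, whatever their values, a set of genes that included MITF, SOX10, AXL, WNT5A, NGFR, EGFR, TGFBI, CDKN2A, CDKN1A, VIM, CDH1, CDH2 and FN1. Some genes picked by the rule are not described in the text.

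Alternatives were scaling by DESeq2's size factors or the upper quartile, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, leaving out each library in turn, and the replicate number as a block. For the lists they also included camera with an estimated correlation and fry. Chosen after seeing the data were a correction of each library for transcript GC content by a lowess curve, and the member counts of each list without GFP replicate 1, the library that lay apart. GC content came from GENCODE transcripts matched by symbol or synonym, for 94.6% of tested genes.

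The tests were checked on simulated counts drawn from the means and sizes of these libraries for BMI1 against GFP, over 14920 genes of which 195 were changed. The edgeR test recovered 74.6% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 98.4% of those changed 4-fold, and 5.17% of its calls were false. The simulated changes alternated between rises and falls, and their share was far below the 26.4% of genes called in the data. These rates therefore do not cover data in which most large changes are rises. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.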

Results

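RNA sequencing was carried out on A375, an established human melanoma cell line with an activating BRAF mutation. Cells carried a lentivirus for GFP, the control, or for murine BMI1, a RING finger subunit of Polycomb repressive complex 1. There were 3 libraries per group. The estimated counts summed to 20692385, 25287464 and 30388937 in GFP replicates 1, 2 and 3, and to 22333840, 20221432 and 24557089 in BMI1 replicates 1, 2 and 3. Between 14750 and 15173 genes per library had at least 10 counts. EEF1A1, a translation elongation factor, was the most abundant gene in each library and took between 1.17% and 1.32% of the total. The first principal component of log2 CPM, counts scaled to a common library size, held 68.4% of the variance and parted the groups. The second held 12.2%, and GFP replicate 1 lay apart on it, at 26.0, with GFP replicates 2 and 3 at -12.4 and -12.2. Counts of libraries of the same group differed by more than sampling noise in each pair, with a mean chi-square per gene between 2.25 for GFP replicates 2 and 3 and 11.7 for GFP replicates 1 and 3, so no library was treated as a repeat of another. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

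The comparison of BMI1 with GFP cells asked which genes changed in melanoma cells given a BMI1 transgene, and in particular whether genes tied to invasion, metastasis and drug resistance moved. The BMI1 row itself rose from 89.4 ± 6.87 CPM in the GFP libraries to 515 ± 8.51 CPM in the BMI1 libraries (SD, n = 3). By library it stood at 81.5, 92.7 and 94.0 CPM in GFP replicates 1, 2 and 3 and at 518, 522 and 506 CPM in BMI1 replicates 1, 2 and 3. The change was 5.76-fold, a log2 fold change of 2.53 (SE 0.06, edgeR adjusted p = 2.59e-11). Because the transgene is murine and the counts were made on a human reference, this row holds the endogenous transcript together with those murine reads that aligned to the human gene, and the fold is not a measure of total BMI1 transcript.

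The rises in the BMI1 cells were larger and more frequent than the falls. FN1, which encodes the matrix protein fibronectin, rose 9.39-fold, from 80.6 ± 0.20 to 757 ± 4.75 CPM (log2 fold change 3.23, SE 0.04, edgeR adjusted p = 1.51e-13). IL8, which encodes a neutrophil-attracting chemokine, rose 17.2-fold, from 4.8 ± 0.82 to 84.1 ± 13.0 CPM (edgeR adjusted p = 6.63e-10). PXDN, which encodes the basement membrane crosslinking enzyme peroxidasin, rose from 6.66 ± 0.23 to 135 ± 1.35 CPM, a log2 fold change of 4.35. DNAH9, an axonemal dynein heavy chain, had the largest fall among the genes picked by the naming rule, from 32.9 ± 1.79 to 9.09 ± 0.69 CPM, a log2 fold change of -1.85 (edgeR adjusted p = 4.61e-09).

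By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3986 of 15079 tested genes changed (26.4%), of which 2581 rose and 1405 fell. Among genes changed by at least 2-fold, 744 rose and 87 fell, so that 89.5% were rises (95% Clopper-Pearson interval 87.2% to 91.5%). That interval treats genes as independent draws, which they are not, and does not cover the spread between libraries. At 4-fold, 229 rose and 12 fell. The 3 libraries of each group did not overlap in CPM for 742 of the 744 rises and 84 of the 87 falls, and for 40.1% of all tested genes, against 10% by chance. Many of these genes stood at low levels. Mean GFP CPM was under 1 for 342 of the 744 rises, and 216 of the 744 reached at least 10 CPM in the BMI1 cells. Mean BMI1 CPM was under 1 for 59 of the 87 falls, and 6 of the 87 had at least 10 CPM in the GFP cells. The changed genes differed in base composition. The median transcript GC content was 58.3% for genes raised at least 2-fold, 45.4% for those lowered at least 2-fold and 50.1% for all tested genes. The count of lowered genes without GFP replicate 1 was 2451 in place of 1405. It was 769 and 885 without GFP replicates 2 and 3, 727 and 711 without BMI1 replicates 1 and 3, and 2390 after correction for GC content. The 87 genes lowered at least 2-fold became 131 with no filter on low counts and 50 with a CPM of at least 1 required in 3 libraries. TEX101 and LOC100216546, named after their values were seen, were counted among the falls through GFP replicate 1 alone, TEX101 at 370 CPM against 5.25 and 5.14 in GFP replicates 2 and 3 and LOC100216546 at 356 CPM against 18.4 and 17.8. Both are among the 6 falls with at least 10 CPM in the GFP cells and among the 12 falls at 4-fold.

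**Figure D1:**
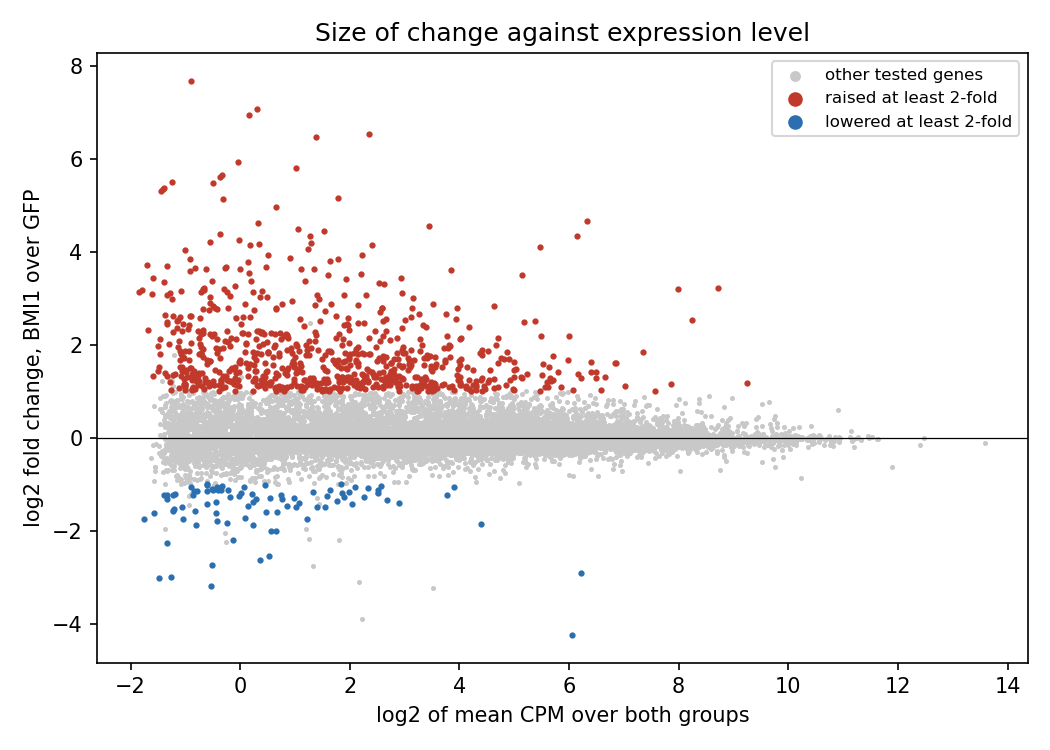
Log2 fold change of BMI1 over GFP (vertical axis) against the log2 of mean CPM over both groups (horizontal axis) for the 15079 tested genes. Red points are the 744 genes raised at least 2-fold, blue points the 87 lowered at least 2-fold, and grey points all others; the red points are more numerous and reach larger changes than the blue ones.

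The steepest rises picked by the naming rule were in genes close to the detection floor in the GFP cells. BAI1, an adhesion G protein-coupled receptor, had a log2 fold change of 6.53 (SE 0.32), with 8 counts over the GFP libraries and 685 over the BMI1 libraries. Leaving out a library moved it to between 5.97 (without GFP replicate 2) and 7.69 (without GFP replicate 3). IGF2, the imprinted insulin-like growth factor gene, had 4 and 348 counts and a log2 fold change of 6.48 (SE 0.30). CACNG7, a calcium channel gamma subunit, rose by 5.15 on the log2 scale, from 14 to 450 counts. TSPAN18, ARHGEF16, ELFN2, SYT7, TRPA1 and ATP2B2 rose by between 3.81 and 4.55 on the log2 scale and reached between 5.52 and 20.8 CPM in the BMI1 cells. TRPA1, at 3.84, ran from 3.42 to 4.53 on leaving out a library. Among falls, the potassium channel KCNJ2, the glutamate transporter SLC1A3 and the sialyltransferase ST8SIA4 had log2 fold changes of -1.42, -1.39 and -1.24. ID4, an inhibitor of helix-loop-helix transcription factors, and HMGN5, a nucleosome-binding protein, stood at -1.17 and -1.18. C1orf114, SPRYD5, ITIH6, NAP1L3, ARPP21 and AZGP1 lay between -1.33 and -1.08.

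Apart from BMI1, most Polycomb genes moved little. Of 25 subunits of Polycomb repressive complex 1, 7 rose and 18 did not pass, and the same numbers held when adjusted over the list alone (camera adjusted p = 0.187). Without GFP replicate 1, 7 rose and 2 fell. Besides BMI1, they included BCORL1, a corepressor, with a log2 fold change of 0.97, and the chromodomain subunit CBX2, with 0.41. AUTS2 had 3.19, from 4 counts over the GFP libraries and 35 over the BMI1 libraries, and ran from 2.51 (without GFP replicate 3) to 3.68 (without GFP replicate 1) on leaving out a library. In Polycomb repressive complex 2, 5 of 11 subunits fell and 6 did not pass, again 5 adjusted over the list alone. The falls were small: the histone methyltransferase EZH2 had a log2 fold change of -0.22, RBBP7 -0.20, AEBP2 -0.24 and MTF2 -0.20. The list was lower by camera (adjusted p = 0.00836) but not with an estimated correlation (adjusted p = 0.123). The calls of EZH2, AEBP2 and MTF2 were each lost without BMI1 replicate 3 (edgeR adjusted p = 0.0558, 0.0584 and 0.0667). Those of AEBP2 and MTF2 were also lost without BMI1 replicate 1 (0.0858 and 0.0914) and without GFP replicate 3 (0.0678 and 0.0574), and that of MTF2 without GFP replicate 2 (0.0712) and after GC correction (0.136). GC correction took the MTF2 log2 fold change to -0.09, while it stayed between -0.18 and -0.20 without any of these libraries.

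Genes held down by Polycomb complexes in many cell types gave a mixed picture. CDKN2A, the INK4A-ARF gene and a classical BMI1 target, was low in both groups, at 3.31 ± 0.60 CPM in GFP and 3.36 ± 0.13 CPM in BMI1 cells, with a log2 fold change of 0.04 (edgeR adjusted p = 0.898). Its neighbour CDKN2B had 0 counts in each library, which allows up to 0.148 CPM in the shallowest library. Of 6 tested genes of the INK4-ARF locus and CDK inhibitor list, 2 rose, 2 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.839). CDKN1A, the p21 gene, rose by 0.34 on the log2 scale and CDKN1C, the p57 gene, by 0.31. CDKN2C and CDKN1B, the p18 and p27 genes, had log2 fold changes of -0.20 and -0.18. The CDKN1B call was lost under upper-quartile scaling (edgeR adjusted p = 0.0539), under the stricter CPM filter (0.0517) and without GFP replicate 2 (0.176), BMI1 replicate 1 (0.148) or BMI1 replicate 3 (0.162). The CDKN2C call was lost without GFP replicate 2 (0.0793) or BMI1 replicates 1 (0.123) or 2 (0.0501). Of 36 HOX genes, which set position along the body axis, 11 rose and 25 did not pass. Adjusted over the list alone, 11 rose and 1 fell. HOXB9, HOXB8 and HOXC8 had log2 fold changes of 0.64, 0.51 and 0.50, and HOXD11, with 57 and 135 counts over the GFP and BMI1 libraries, had 1.41. The HOX list was higher by camera (adjusted p = 0.0179) but not with an estimated correlation (adjusted p = 0.504), after GC correction (0.103), without GFP replicate 3 (0.0773) or without BMI1 replicate 1 (0.0605).

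Genes of the invasive melanoma phenotype rose as a group. Of 43 tested members, 23 rose, 2 fell and 18 did not pass, with 26 and 2 adjusted over the list alone, and the median log2 fold change was 0.28. The list was higher by camera (adjusted p = 2.76e-07) and also with an estimated correlation (adjusted p = 0.0417). The latter value was tied with that of the TGF-beta pathway list through the Benjamini-Hochberg adjustment, and each passed only together with the other. Both lists hold the gene INHBA. INHBA, which encodes the activin A subunit, rose 2.68-fold from 45.6 ± 1.95 to 122 ± 3.66 CPM, and FST, which encodes the activin antagonist follistatin, rose from 82.2 ± 1.79 to 177 ± 6.55 CPM. DKK1, a secreted Wnt antagonist, had a log2 fold change of 2.39. TGFBI, a matrix protein induced by TGF-beta, had 0.89 and rose from 261 ± 8.24 to 484 ± 3.19 CPM. WNT5A, a non-canonical Wnt ligand, had 0.70 (SE 0.06, edgeR adjusted p = 1.53e-06), and EGFR 0.65. The receptor kinase AXL did not pass, with 145 ± 1.96 and 137 ± 2.87 CPM in GFP and BMI1 cells (edgeR adjusted p = 0.221). After GC correction AXL passed, with a log2 fold change of -0.15 (edgeR adjusted p = 0.00819). NGFR, a marker of neural crest-like melanoma cells, had a log2 fold change of 0.22 (edgeR adjusted p = 0.0915) and, without GFP replicate 1, 0.34 (edgeR adjusted p = 0.000872).

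**Figure D2:**
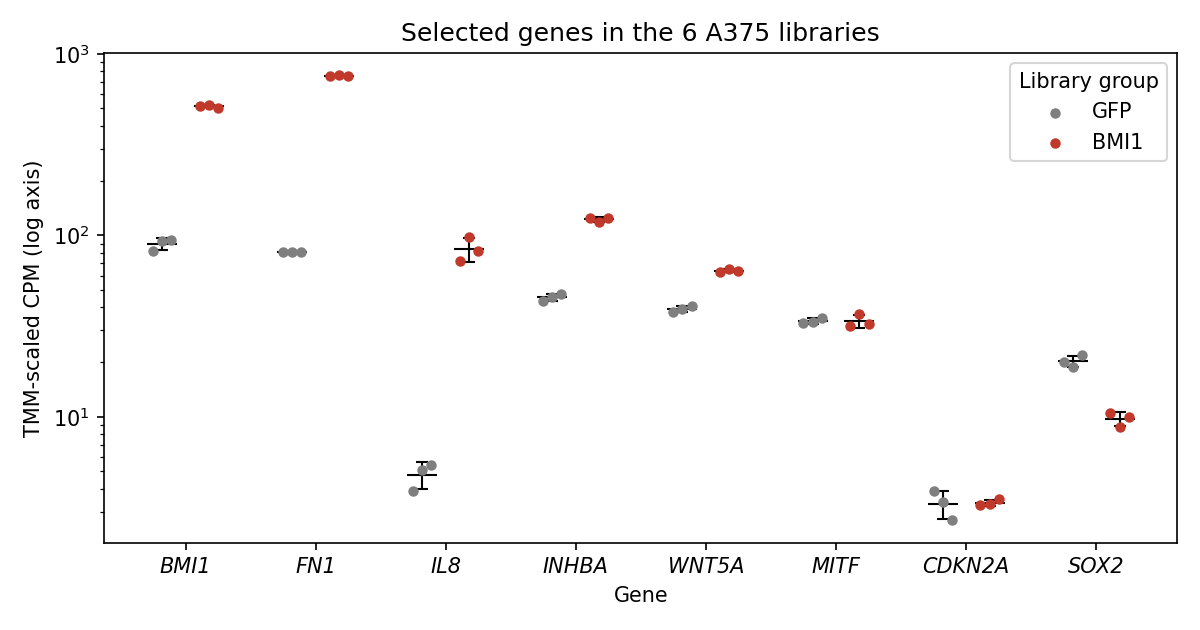
CPM of 8 genes in the 6 A375 libraries (vertical log axis, TMM-scaled CPM; grey GFP, red BMI1); horizontal bars are means and whiskers are SD over 3 libraries. BMI1, FN1, IL8, INHBA and WNT5A were higher in each BMI1 library than in any GFP library, SOX2 was lower, and MITF and CDKN2A overlapped between the groups.

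The master regulators of melanocyte identity did not pass the test. MITF, the lineage transcription factor, stood at 33.7 ± 1.21 CPM in GFP and 33.6 ± 2.76 CPM in BMI1 cells (log2 fold change -0.01, edgeR adjusted p = 0.937). SOX10, another lineage factor, stood at 647 ± 77.5 and 632 ± 41.7 CPM (log2 fold change -0.03, edgeR adjusted p = 0.781) and passed only after GC correction, with a log2 fold change of -0.14 (edgeR adjusted p = 0.0104). Of 29 tested pigmentation genes and MITF targets, out of 38 listed, 12 rose, 3 fell and 14 did not pass, with 13 and 3 adjusted over the list alone. The adhesion molecule CEACAM1 had a log2 fold change of 2.52, the survival gene BCL2A1 2.21, GMPR, an enzyme of purine metabolism, 3.65 from 9 counts over the GFP libraries, and the syntaxin STX7 -0.72. The pigment genes TYR and DCT fell below the count filter, with 1 and 7 counts over all 6 libraries, and so did PMEL with 66. The list was higher by camera (adjusted p = 0.0114) but not with an estimated correlation (adjusted p = 0.123) or without GFP replicate 1 (0.0645).

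Extracellular matrix genes moved upward across several lists. Of 35 epithelial-mesenchymal transition genes, 21 rose, 4 fell and 10 did not pass, with 22 and 7 adjusted over the list alone (camera adjusted p = 5.99e-05, adjusted p = 0.0711 with an estimated correlation). Beside FN1, the matrix protein SPARC rose from 1526 ± 19.0 to 2327 ± 19.4 CPM, the actin-binding TPM1 had a log2 fold change of 0.84, and the fibrillar collagen COL5A1 had 1.77. The classical switch genes did not follow them. VIM, the vimentin gene, had a log2 fold change of -0.16 (edgeR adjusted p = 0.00378), CDH2, the N-cadherin gene, -0.15 (edgeR adjusted p = 0.0672), and CDH1, the E-cadherin gene, 0.72 at under 1 CPM (edgeR adjusted p = 0.0657). CDH2 passed without GFP replicate 1 (edgeR adjusted p = 0.00153), after GC correction (0.0251) and with DESeq2 (0.0405), and CDH1 after GC correction (0.0403). Of 35 collagens and basement membrane genes, 23 rose, 1 fell and 11 did not pass, with 24 and 1 adjusted over the list alone (camera adjusted p = 2.75e-08, adjusted p = 0.143 with an estimated correlation). COL15A1, COL13A1 and COL18A1 had log2 fold changes of 2.79, 1.63 and 1.42. Markers of fibroblasts, a cell type rich in these transcripts, moved the same way: of 6 tested markers 4 rose (5 adjusted over the list alone), FBLN1 by 1.45, PDGFRA by 1.11, LUM by 0.79 and PRRX1 by 0.40 on the log2 scale. Of the 10 listed fibroblast markers, 6 also stand in other lists. In contrast, COL3A1, an abundant fibroblast collagen, stood at 0.11 CPM in GFP and 0.09 CPM in BMI1 cells.

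Receptors for matrix and matrix-remodelling enzymes rose in part. Of 17 integrins, 9 rose, 2 fell and 6 did not pass, the same adjusted over the list alone, led by ITGA11, a collagen receptor subunit, with a log2 fold change of 2.35. ITGA7, ITGB4 and ITGA2 had 1.18, 0.84 and 0.78. The integrin list was higher by camera (adjusted p = 0.00829) but not with an estimated correlation (adjusted p = 0.123) or without BMI1 replicate 2 (0.0505). Of 30 extracellular proteases and inhibitors, 16 rose, 2 fell and 12 did not pass, with 18 and 4 adjusted over the list alone (camera adjusted p = 0.000838, adjusted p = 0.0898 with an estimated correlation). They included the metalloprotease inhibitors TIMP3, from 589 ± 10.1 to 1012 ± 9.23 CPM, and TIMP1, with a log2 fold change of 0.75, next to the plasminogen activator PLAT, with 0.81, and the gelatinase MMP2, with 0.54. Without GFP replicate 1, 4 members of this list fell. Of 26 cadherins and other adhesion molecules, 11 rose, 1 fell and 14 did not pass, with 13 and 3 adjusted over the list alone (camera adjusted p = 0.00829, adjusted p = 0.123 with an estimated correlation), and 3 fell without GFP replicate 1. BCAM, a laminin receptor, had a log2 fold change of 1.47, CDH3, the P-cadherin gene, 2.15, L1CAM 0.64 and CDH13 0.54. Of 31 actin cytoskeleton genes and YAP targets, 11 rose, 3 fell and 17 did not pass, with 13 and 4 adjusted over the list alone (camera adjusted p = 0.214). MYL9, a myosin light chain, ARHGEF17 and ARHGAP29 had log2 fold changes of 1.15, 0.55 and 0.47.

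The TGF-beta pathway was the list with the smallest camera p. Of 41 tested genes, 30 rose, 2 fell and 9 did not pass, with 31 and 2 adjusted over the list alone, a median log2 fold change of 0.58 (camera adjusted p = 1.61e-11, adjusted p = 0.0417 with an estimated correlation). BMP7, a ligand of the family, rose from 6.0 ± 0.64 to 43.6 ± 1.92 CPM. PMEPA1, a feedback inhibitor, rose from 71.7 ± 1.90 to 256 ± 12.5 CPM, and ID1, a target of BMP signalling, had a log2 fold change of 1.41. The 2 falls were ID4 and the signal transducer SMAD4, at -0.25, the latter named after its value was seen. Of 29 non-canonical Wnt genes, 14 rose and 15 did not pass, with 15 rises adjusted over the list alone (camera adjusted p = 0.000123, adjusted p = 0.123 with an estimated correlation). The formin DAAM2, the ligand WNT5B and the planar polarity gene VANGL2 had log2 fold changes of 1.37, 2.09 and 0.85. Of 17 tested canonical Wnt genes out of 30 listed, 12 rose, 2 fell and 3 did not pass, the same adjusted over the list alone, with a median of 0.95 (camera adjusted p = 0.000144, adjusted p = 0.0854 with an estimated correlation). They included secreted antagonists beside a transcription factor: DKK1, DKK3 at 0.95, NOTUM at 3.55 from 13 counts over the GFP libraries, and TCF7 at 1.72.

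Genes tied to drug response gave separate results by class. Of 26 receptor kinases linked to drug resistance, 12 rose, 3 fell and 11 did not pass, with 17 and 4 adjusted over the list alone (camera adjusted p = 0.000838, adjusted p = 0.276 with an estimated correlation). EPHB2, FLT1, FGFR1 and FGFR4 had log2 fold changes of 1.28, 1.24, 1.09 and 0.88. Of 25 drug efflux transporters and aldehyde dehydrogenases, 9 rose, 4 fell and 12 did not pass, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.187). ABCC2, a drug export pump, fell from 45.1 ± 1.25 to 23.1 ± 1.54 CPM, while ABCB4, ALDH1B1 and ALDH2 had log2 fold changes of 1.35, 0.49 and 0.40. Of 28 genes of MAPK pathway output, 5 rose, 6 fell and 17 did not pass (camera adjusted p = 0.474). Adjusted over the list alone 8 rose and 6 fell, and 8 rose without GFP replicate 1. Apart from IL8, the early response gene EGR3 rose from 20.2 ± 1.06 to 49.7 ± 1.27 CPM, the ephrin receptor EPHA4 had a log2 fold change of 0.73 and DUSP2, a MAP kinase phosphatase, 0.69. Of 16 BCL2 family genes, 6 rose and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.137). The rises included both the survival gene BCL2A1 and the death-promoting BCL2L11 and BOK, at 0.47 and 0.70, and HRK, at 2.01 with 18 and 65 counts over the GFP and BMI1 libraries.

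The cytokine and antigen presentation lists were higher by camera with the preset correlation but not with an estimated one. Of 25 NF-kB targets and cytokines, 13 rose, 2 fell and 10 did not pass, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.00199, adjusted p = 0.123 with an estimated correlation). Next to IL8, the related chemokine CXCL1 rose from 4.47 ± 0.31 to 26.1 ± 1.83 CPM, and IL11 and CSF1 had log2 fold changes of 0.78 and 0.55. Of 26 antigen presentation genes, 17 rose and 9 did not pass, with 20 rises adjusted over the list alone (camera adjusted p = 5.80e-06, adjusted p = 0.127 with an estimated correlation). The class I genes HLA-B and HLA-C had log2 fold changes of 0.68 and 0.33, and their transactivator NLRC5 had 0.45. Of 38 interferon response genes, 10 rose, 1 fell and 27 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.505), and 4 fell without GFP replicate 1. IFITM2, MX1, IFITM3 and PARP9 had 0.85, 0.56, 0.31 and 0.25. The HLA, IFITM and CXCL1 rows belong to families of closely similar genes that can share reads, so their single values are uncertain.

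Neural crest genes split. Of 24 tested, 10 rose, 6 fell and 8 did not pass, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.245). NES, the intermediate filament nestin, rose from 144 ± 4.87 to 322 ± 8.43 CPM, and the transcription factor TFAP2B had a log2 fold change of 0.56. The stem cell factor SOX2 fell from 20.3 ± 1.45 to 9.76 ± 0.86 CPM and the retinoid receptor RXRG had -0.69. Of 35 cell cycle genes of G2/M, 1 rose, 5 fell and 29 did not pass, with 1 and 4 adjusted over the list alone. CCNB1, CCNA2, AURKA and CKS2 had log2 fold changes of -0.24, -0.23, -0.21 and -0.29. The CKS2 call was lost without GFP replicate 2 (edgeR adjusted p = 0.0591) and without BMI1 replicate 1 (0.0710). The G2/M list was lower by camera (adjusted p = 0.00836) but not with an estimated correlation (adjusted p = 0.276) or after GC correction (0.127), and 2 members rose and 11 fell without GFP replicate 1. Of 30 cell cycle genes of G1/S, 4 rose, 1 fell and 25 did not pass, with 3 and 1 adjusted over the list alone and 6 and 2 without GFP replicate 1 (camera adjusted p = 0.572). E2F2, E2F1 and the ribonucleotide reductase subunit RRM2 had 0.48, 0.35 and 0.23, and TYMS -0.17, a call lost without GFP replicate 2 (edgeR adjusted p = 0.0822) or BMI1 replicate 1 (0.0670).

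No stress or metabolic list passed camera. Of 24 p53 targets, 4 rose, 4 fell and 16 did not pass, with 4 and 5 adjusted over the list alone and 6 and 7 without GFP replicate 1. PHLDA3, DDB2 and CCNG1 had log2 fold changes of 0.37, -0.23 and -0.30. The PHLDA3 call was lost without BMI1 replicate 3 (edgeR adjusted p = 0.0582) and that of CCNG1 without BMI1 replicate 1 (0.0569) or 3 (0.0532). The median of the list was -0.05 and its mean 0.003, with camera pointing down (adjusted p = 0.474). Of 28 hypoxia genes, 6 rose, 5 fell and 17 did not pass, the same adjusted over the list alone, with a median of 0.01 where camera pointed down (adjusted p = 0.835). The glycolytic enzyme PGK1 fell from 1056 ± 52.4 to 681 ± 12.9 CPM, while P4HA2, ALDOC and PFKFB3 had 0.60, 0.54 and 0.38. Of 28 genes of the unfolded protein and amino acid stress responses, 9 rose, 5 fell and 14 did not pass, with 11 and 5 adjusted over the list alone (camera adjusted p = 0.294). CRELD2 had 0.78, and the stress factor DDIT3 and the amino acid transporters SLC7A11 and SLC7A1 had -0.52, -0.47 and -0.31. Of 24 cholesterol synthesis genes, 2 rose, 5 fell and 17 did not pass, the same adjusted over the list alone (camera adjusted p = 0.187), and 4 rose and 7 fell without GFP replicate 1. ACAT2 had -0.39 and SC5DL -0.47. Of 32 oxidative phosphorylation genes, COX5B passed, at 0.15, and 31 did not (camera adjusted p = 0.713). Adjusted over the list alone 0 passed, and the COX5B call was also lost with DESeq2 (adjusted p = 0.0509) and on leaving out any library but GFP replicate 1 (edgeR adjusted p between 0.0745 and 0.187). Without GFP replicate 1, 3 rose and 3 fell. Of 45 cytosolic ribosomal proteins, 0 passed in edgeR, in DESeq2 or in limma-voom, 2 had an unadjusted edgeR p under 0.05 (camera adjusted p = 0.312), and 8 fell without GFP replicate 1.

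Markers of keratinocytes, leukocytes and endothelium were tested where they passed the count filter. Of 10 keratinocyte markers 4 were tested, of which 2 rose and 0 fell, DSC3 by 1.11 and KRT14 by 0.55 on the log2 scale. KRT14 lost its call without GFP replicate 3 (edgeR adjusted p = 0.0683), BMI1 replicate 1 (0.0556) or BMI1 replicate 2 (0.0503). Of 10 leukocyte markers 2 were tested, LYZ with a log2 fold change of -0.68 and CD68 with 0.25. CD68 lost its call under DESeq2 size factors (edgeR adjusted p = 0.0507) and without GFP replicates 2 (0.103) or 3 (0.170) or BMI1 replicates 1 (0.119) or 3 (0.162). Of 10 endothelial markers 5 were tested, of which VWF rose by 0.85 and KDR had -0.83. The counts for these 3 marker lists were the same adjusted over the list alone.

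**Figure D3:**
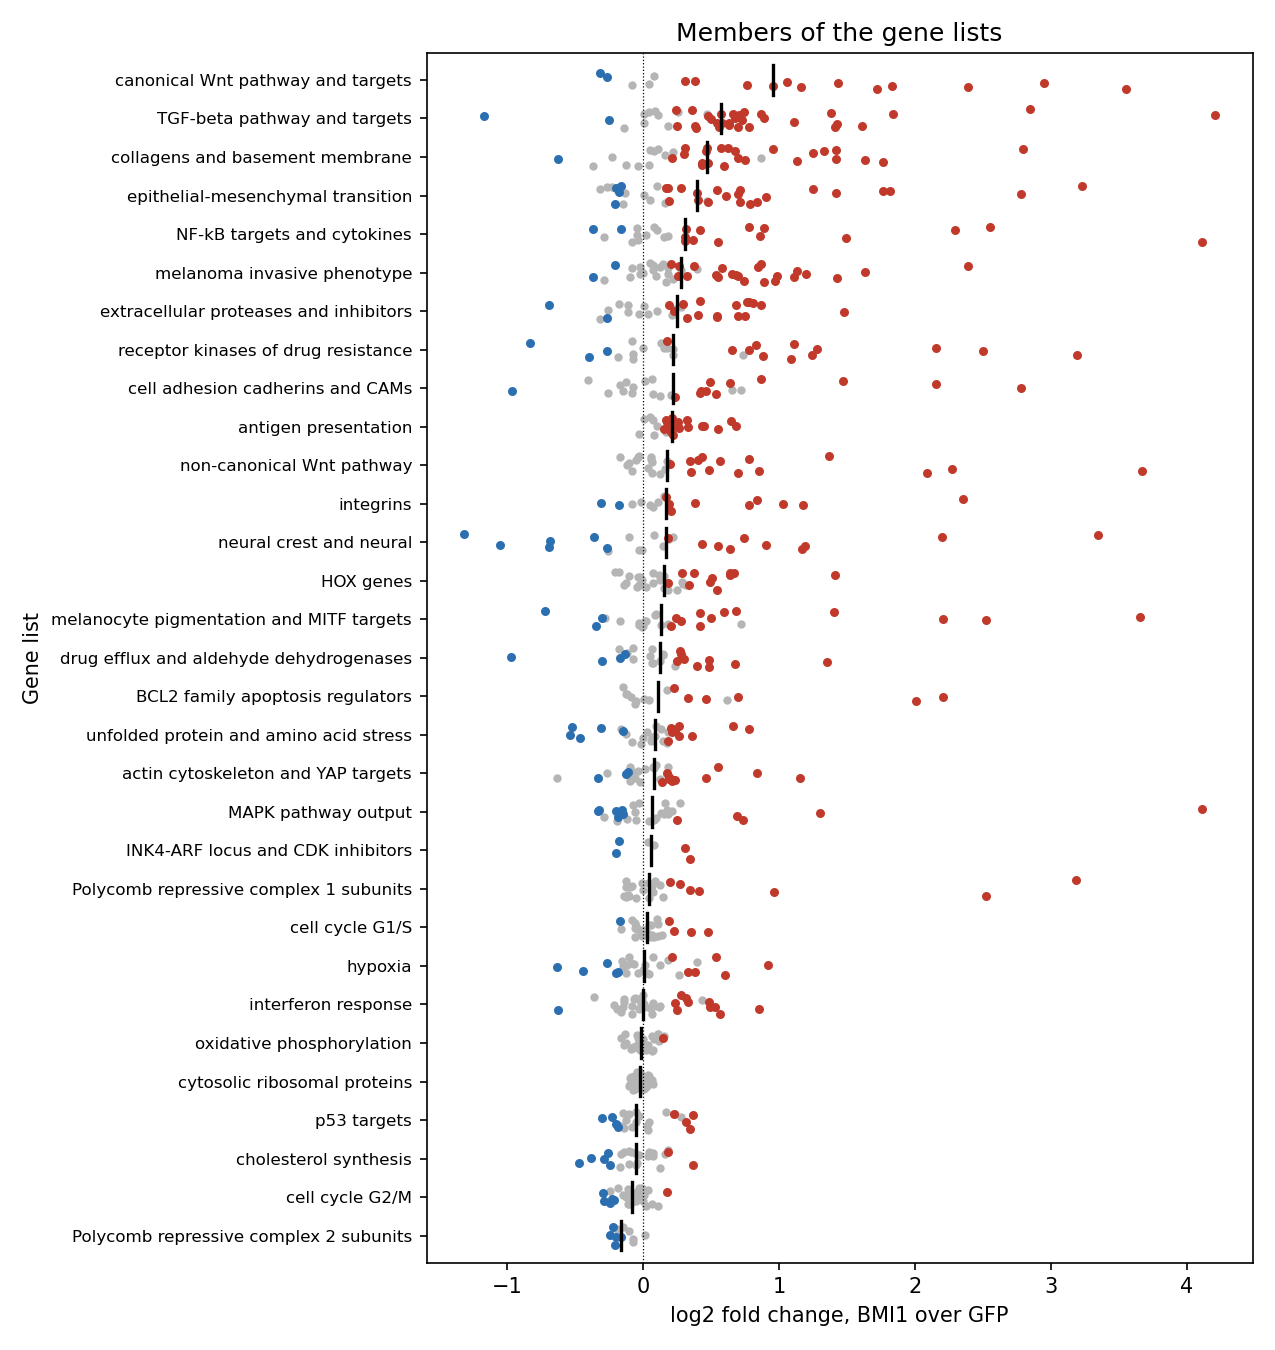
Log2 fold change of BMI1 over GFP (horizontal axis) for each tested member of the 31 gene lists (rows, ordered by median). Red points rose, blue points fell and grey points did not pass edgeR's test at an adjusted p of 0.05; black bars are medians, which run from -0.16 for Polycomb repressive complex 2 to 0.95 for the canonical Wnt list.

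Over the 31 lists that are not cell type markers, 14 were higher and 2 lower by camera with a preset correlation of 0.01. With the correlation estimated from each list, 2 held, the invasive melanoma phenotype and the TGF-beta pathway. These 2 lists share INHBA. Their unadjusted camera p with an estimated correlation differed, at 0.00269 and 0.00244. The Benjamini-Hochberg adjustment gave both 0.0417, and through it each passed only together with the other. Not every list that was lost had an estimated correlation above the preset. It was -0.017 for epithelial-mesenchymal transition and -0.015 for canonical Wnt, against 0.18 for collagens and basement membrane. For the first 2 of these lists, an estimate below the preset of 0.01 cannot weaken the result through correlation. Even so, their unadjusted camera p with the estimate was 0.00688 and 0.0110. Their loss came with the change to a test that estimates the correlation, not from correlated members. Losing a list under an estimated correlation is therefore not by itself a sign that its members are correlated.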

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

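Chosen only after the data were seen were the GC correction and the list counts without GFP replicate 1. BMI1 kept its rise past the threshold under each alternative. Of 3986 changed genes, the count ran from 3428 with DESeq2 to 4153 with no low-count filter over the planned settings using all libraries, was 5572 after GC correction and lay between 2757 and 5644 on leaving out a library. The count lowered was 2390 after GC correction and, leaving out a library, from 711 (without BMI1 replicate 3) to 2451 (without GFP replicate 1). The genes lowered at least 2-fold numbered 131 with no filter and 50 with the stricter filter, where fewer genes were tested. Otherwise the cause was not tested. The 16 lists that passed became 2 with an estimated correlation and 25 with fry, which does not compare a list with other genes. Of 2125 values for 152 named genes under the alternatives, 2068 kept sign and side of the threshold, 42 lost the threshold, 8 gained it and 7 reversed sign. For lists, 338 of 372 kept both, 20 lost the threshold, 9 gained it and 5 reversed.

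None of the genes that reversed had passed. MITF had a log2 fold change of 0.0316 after GC correction and from -0.0755 to 0.0311 on leaving out a library. The gene SOX10 ran from -0.0943 to 0.0743, and CDKN2A was -0.0563 after GC correction and ran from -0.107 to 0.164. The lists that reversed had not passed either. The INK4-ARF locus and CDK inhibitors had an adjusted p of 0.756 after GC correction and from 0.580 to 0.975 on leaving out a library. The hypoxia list had 0.151 with fry (range 0.151 to 0.975 over its alternatives), and oxidative phosphorylation had 0.904 with fry and 0.951 after GC correction (range 0.433 to 0.951).

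The replicate numbers are shared by the groups, but deviations of same-numbered libraries correlated at 0.07, 0.09 and -0.06, and not every library correlated best with its own number. With the replicate block, 3988 genes changed, 3772 of them among the 3986, and 844 by at least 2-fold. NGFR then passed (edgeR adjusted p = 0.0391) and COX5B did not (0.0694).

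Genes near the floor are the ones that depth limits: CDKN2B and KIT had 0 counts, and the fold of IGF2 rests on 4 counts in the GFP libraries.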

Other observations

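The gene families, the GC correction, the genomic DNA, histone, label, depth and fibroblast tests, and the question of separate cell lines were chosen only after the data were seen, while the other scalings and the splits of the libraries were fixed before.

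Voltage-gated calcium channel subunits had the largest median log2 fold change among 16 gene families grouped by symbol after the data were seen. The largest rises, CACNG7 of this family among them, were known by then, so the family p-values are not independent evidence. Of 17 tested, 11 rose and 1 fell, with a median log2 fold change of 1.04 (camera adjusted p = 8.07e-06, adjusted p = 0.136 with an estimated correlation, 7.24e-05 after GC correction). CACNA1H, a T-type channel, rose from 0.27 ± 0.10 to 4.46 ± 0.21 CPM (SD, n = 3), and CACNA1D, an L-type channel, from 6.21 ± 0.26 to 12.8 ± 0.65 CPM. CACNA1E, an R-type channel, fell from 2.48 ± 0.30 to 0.41 ± 0.07 CPM. Of 53 potassium channel subunits, 18 rose and 2 fell (camera adjusted p = 0.0128, adjusted p = 0.150 with an estimated correlation), including KCNN1, from 1.88 ± 0.05 to 8.28 ± 0.27 CPM, and KCNMA1, from 18.3 ± 1.2 to 33.0 ± 2.04 CPM. That ion channel families may have risen as sets is a hypothesis that the strictest test leaves open, since the lowest adjusted p over the channel families was 0.136 with an estimated correlation.

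Ephrins and Eph receptors, cell contact signals, had 9 rises and 1 fall among 16 tested (camera adjusted p = 0.000231, adjusted p = 0.150 with an estimated correlation). EFNB3 rose from 7.72 ± 0.42 to 15.6 ± 1.84 CPM and EFNB1 from 5.35 ± 0.04 to 10.3 ± 0.58 CPM. Of 19 tetraspanins 8 rose (camera adjusted p = 0.0128, adjusted p = 0.192 with an estimated correlation), TSPAN9 from 18.1 ± 0.44 to 27.8 ± 1.45 CPM. Zinc finger genes moved the other way: of 503, 15 rose and 98 fell, with a median log2 fold change of -0.12 (camera adjusted p = 6.58e-07, adjusted p = 0.150 with an estimated correlation, 1.37e-05 after GC correction). ZNF217 fell from 151 ± 6.14 to 115 ± 0.85 CPM. Many zinc finger genes are close copies of each other, so reads may be split between them and their single values are uncertain. Semaphorins and plexins (12 rises and 3 falls among 26), proteasome subunits (3 falls among 38) and mitochondrial ribosomal proteins (2 rises and 6 falls among 79) also passed camera with the preset correlation (adjusted p of 0.0179, 0.0128 and 0.0128, each 0.213 with an estimated correlation), and semaphorins and plexins no longer did after GC correction (adjusted p = 0.154). The other 8 families did not pass.

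Rises outnumbered falls among genes changed at least 2-fold, 744 against 87. GC-dependent recovery of transcripts was tested because raised genes looked rich in GC, and log2 fold change did go with GC content across genes, which are not independent replicates (Spearman rho 0.37). Among genes with a GC value, a correction that lowered this to 0.06 took 729 rises and 79 falls to 700 and 86, 89.1% rises, which argues against GC as the whole cause of the excess at 2-fold. Over changed genes of any size, rises made up 64.8% among all tested genes and 57.1% after correction among those with a GC value (3182 rises and 2390 falls). Genomic DNA in the BMI1 libraries would have filled empty rows, yet 84.0% of rows empty in the GFP libraries were also empty in the BMI1 libraries, against 84.1% for the mirror share. These shares were not adjusted for depth. Of 4127 rows empty in GFP, 27 had at least 10 counts over the BMI1 libraries, against 8 of 4123 in the mirror. The scaling of the libraries stays open: the lowest share under the 2 other scalings was 89.3%, but they moved the median log2 fold change by at most 0.008, too little to test it. An effect of BMI1 itself stays open as an untested hypothesis.

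GFP replicate 1 held more of several RNAs that lack a poly(A) tail, with RMRP at 59.7 CPM against 1.15 and 1.36 in GFP replicates 2 and 3 and RPPH1 at 25.9 against 0.04 and 0.30. Carry-over of such RNA may explain this. A separate class, 19 replication-dependent histone rows, had a median log2 ratio of 0.70 to the other 2 GFP libraries. This was above 100% of 10000 random lists of like expression. In BMI1 replicates 1, 2 and 3 the ratio to the rest of their group was 0.04, -0.15 and 0.11. These values were above 76.0%, 1.48% and 95.2% of random lists, so the percentile alone does not mark GFP replicate 1. Its ratio was the largest of any library. Its BMI1 level was 87.3% of the mean of the other GFP libraries, which argues against a wrong label, and the library with the lowest total, BMI1 replicate 2, had a histone ratio of -0.15, which argues against low depth. No biological explanation was tested.

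FN1 and collagens were higher in the BMI1 libraries, beside markers of fibroblasts. Fibroblasts among the BMI1 cells would bring their abundant transcripts, but the highest gain among COL1A2, COL3A1, DCN and THY1 was 0.457 CPM, against 676 CPM for FN1, which argues against them. A difference between the 2 transduced cell lines other than the transgene cannot be told apart from BMI1, because the labels give 1 control group and do not say whether the libraries of a group came from separate transductions.

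The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 3986 changed genes in edgeR, and the highest of the others gave 0. Each of the others set libraries of both groups on each side, which widens the spread within a side, so few calls were likely in advance. Among those others, the number of genes with an unadjusted edgeR p under 0.05 ran from 67 to 2558, and limma-voom called at most 1 gene. The split that set GFP replicate 1 with BMI1 replicates 1 and 3 gave the 2558, and DESeq2 called 347 genes there.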
